A study of Mus musculus with 10 samples.

How the data were processed

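Total RNA was sequenced from live CD45-negative, EpCAM-positive cells of the ileum of 10 mice, 5 per genotype, each with 3 males and 2 females. Genotypes follow the sample labels, which differ from the series text in giving Cre for dIEC. Libraries were made with a stranded kit after removal of ribosomal RNA, per the labels' protocols. The deposited table holds raw counts per gene, and reads were aligned with Novoalign to mm10, per the submitters' processing notes. The counting program, its use of strand and the annotation are not given in the sources used here, so genes that overlap or have near-identical copies, such as the haemoglobin genes and the Gbp family, are uncertain. Every one of the 13932 listed genes reaches at least 10 counts in 1 library or more, as seen in the values.

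Genes were identified by Ensembl identifier. The table gives no symbol for 133 genes, and 20 symbols that had turned into dates were replaced by identifier. Coordinates come from GENCODE on GRCm38, the assembly also called mm10. Pairs of libraries within a group differed far beyond sampling noise (chi-square over degrees of freedom 17.0 to 163), so none was counted as a repeat. Totals of 9174101 to 13484363 counts set the precision, and counting error is only part of the spread between mice.

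The tests ran in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. filterByExpr kept 12477 genes (89.6%), and TMM factors scaled the libraries. edgeR's quasi-likelihood test with robust estimation, on sex plus genotype, gave the genotype and sex comparisons, and a model with their product gave the interaction. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The standard error is the size of the log2 fold change over the square root of F. CPM values use TMM-scaled totals, and log2 CPM a prior count of 2. For H2-Ab1, an exact permutation test covered all 252 assignments.

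The design, the 32 gene lists and most alternatives were set before the data were examined. Lists with at least 3 tested genes were compared with other genes by camera on voom values, with a preset correlation of 0.01 and with an estimated one. The T cell list had too few genes to test. Genes were named by a rule. It takes the MHC class II genes. It takes up to 12 genes per direction past the threshold with a mean of at least 1 CPM, leaving out gene models and receptor segments, or the 10 with the smallest p where fewer than 5 pass. It also takes up to 4 members of every other list, and up to 5 genes per direction for the interaction. The text gives part of those it takes, picked for interest once values were known.

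The method was tested on simulated counts for 12477 genes, 200 of them changed. For dIEC against WT it recovered 4.62% of genes changed 1.5-fold, 41.8% of those changed 2-fold and 92.3% of those changed 4-fold, and 14 of 105 calls were false. For the sexes it recovered 84.6% at 4-fold, and for the interaction 4.55% at 4-fold. Simulated genes varied independently, without differences that many genes share between libraries. Alternatives were other size factors, library size only, DESeq2, limma voom with sample weights, the older edgeR estimator, 2 other filters, a threshold of 0.1, other covariates, each sex or genotype alone, and leaving out each library. Added after the data were seen were a proliferation score as covariate, the first residual component as covariate, a fit without dIEC 7 and dIEC 9, and DESeq2 on every listed gene. The planned DESeq2 fit used its own size factors on the filtered genes.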

Results

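RNA was sequenced from epithelial cells of the mouse ileum, the last part of the small intestine. The cells were sorted as live, negative for the leukocyte marker CD45 and positive for the epithelial marker EpCAM. In 5 mice, called dIEC here, H2-Ab1, the gene of an MHC class II beta chain, was to be deleted by Cre recombinase under the villin promoter, which is active in intestinal epithelium. The sample labels give Cre for these 5, while the series text gives no Cre for either genotype. The other 5 mice, called WT, carried, per both, the same floxed gene without Cre. Each genotype had 3 males and 2 females, and each library came from 1 mouse. The total count per library ran from 9174101 to 13484363 over 13932 listed genes, of which 12477 were tested.

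The libraries differed most along 1 axis that did not follow genotype. The first principal component held 50.1% of the variance. The mean log2 CPM (counts scaled by library size) of the proliferation genes ran from 2.80 in dIEC female 7 to 5.36 in dIEC female 9, so the 2 dIEC females lay at opposite ends. Libraries with more proliferation transcripts had fewer transcripts of mature enterocytes, the absorptive cells of the villus (Pearson r = -0.913, permutation p = 0.00022, n = 10).

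**Figure D1:**
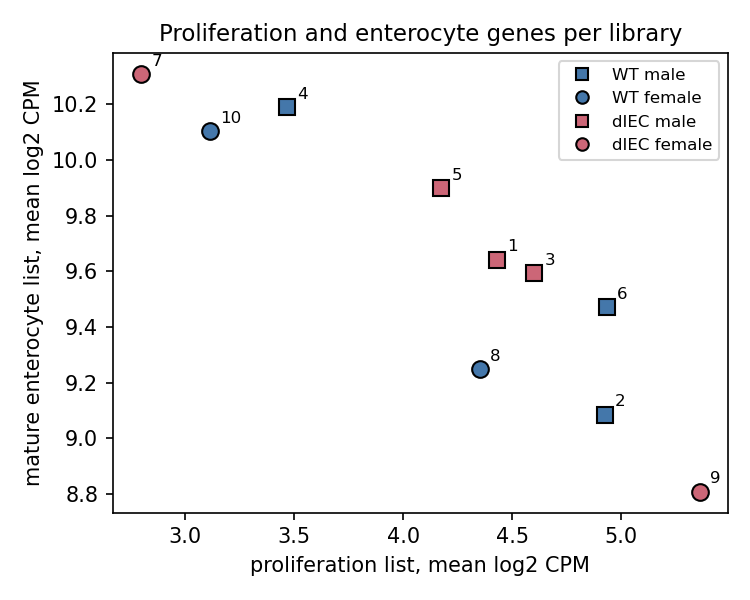
Mean log2 CPM of the mature enterocyte list against that of the proliferation list in 10 libraries, with colour for genotype, shape for sex and the replicate number beside each point. dIEC female 7 has the lowest proliferation value, 2.80, and dIEC female 9 the highest, 5.36.

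The first comparison asked how the epithelial transcriptome differed between dIEC and WT. By the sample labels all 5 dIEC mice carried Cre and no WT mouse did. Effects of the deletion and of Cre itself therefore cannot be told apart. The deleted gene was measured first. H2-Ab1 (ENSMUSG00000073421; mm10 chromosome 17, 34257689 to 34269419) fell from 208 ± 117 CPM in WT to 2.14 ± 0.96 CPM in dIEC (SD, n = 5 each), 1.03% of the WT level. The lowest WT library had 62.8 CPM and the highest dIEC library 3.11 CPM. The log2 fold change was -6.39 (SE 0.49, edgeR quasi-likelihood adjusted p = 0.000593), and the exact two-sided permutation test over 252 assignments gave p = 0.00794, the smallest it can give.

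One other gene passed. Mt1 (ENSMUSG00000031765; chromosome 8, 94179082 to 94180327), which encodes a metal-binding metallothionein, rose from 26.7 ± 9.52 CPM in WT to 289 ± 36.4 CPM in dIEC (SD, n = 5 each; fitted log2 fold change 3.45, SE 0.24, edgeR adjusted p = 0.000401). All 5 dIEC libraries lay between 248 and 330 CPM and all 5 WT libraries between 16.2 and 41.7 CPM. Its neighbour Mt2, chosen after its values were seen, did not pass (1.98 ± 1.67 against 4.11 ± 2.47 CPM; exact permutation p = 0.111, n = 5 each). Thus 2 of 12477 genes passed the threshold. In the simulation 4.62% of genes changed 1.5-fold and 41.8% of those changed 2-fold were recovered, so smaller changes may have been missed. At an unadjusted p under 0.05 there were 373 genes, against 624 given by chance, and DESeq2 called 4 genes.

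**Figure D2:**
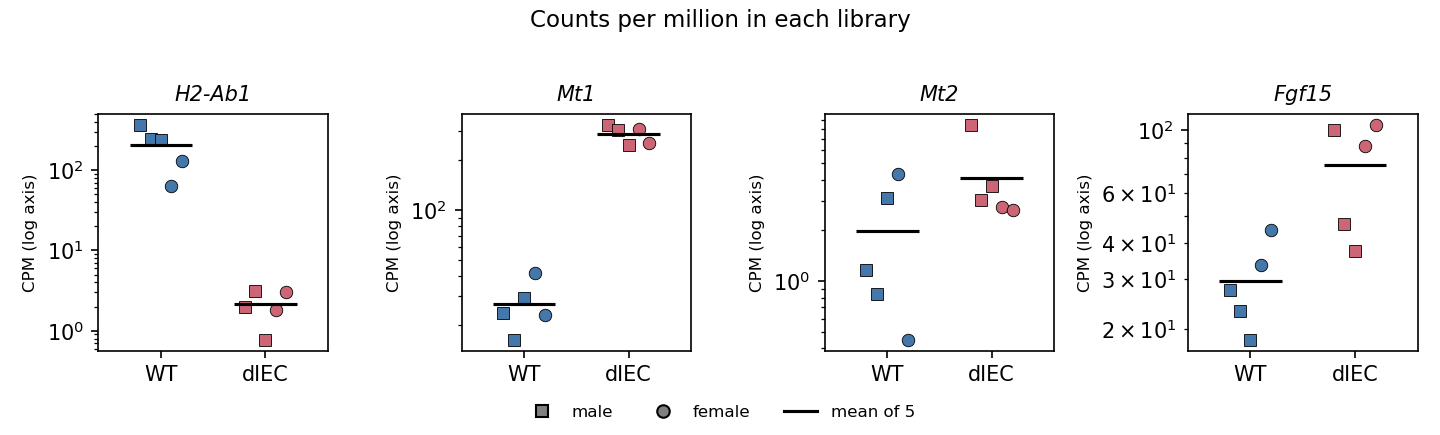
CPM on a log axis for H2-Ab1, Mt1, Mt2 and Fgf15 in each library of WT and dIEC, with squares for males, circles for females and a line for the mean of 5. H2-Ab1 and Mt1 do not overlap between genotypes, with Mt1 at 248 to 330 CPM in dIEC and 16.2 to 41.7 CPM in WT.

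The genes next in rank did not pass the threshold, and their values are given as such. Fgf15, the ileal hormone that represses bile acid synthesis in the liver, had a log2 fold change of 1.37 (SE 0.26; 29.4 ± 10.1 CPM in WT and 75.3 ± 31.1 CPM in dIEC; edgeR adjusted p = 0.9998), and DESeq2 called it (adjusted p = 0.00321). Abcc3, an exporter of bile acid and other conjugates, was at 117 ± 9.45 CPM in WT and 82.0 ± 13.7 CPM in dIEC (log2 fold change -0.51, SE 0.14). Adjusted over the list alone, Fgf15 rose and Abcc3 fell among the 10 tested genes of ileal bile acid handling. The list, fixed in advance, was not called as a whole (5 genes higher and 5 lower; camera adjusted p = 0.759 with the preset correlation). The creatine kinase gene Ckb had a log2 fold change of -1.06 (SE 0.27) and the pro-apoptotic gene Bid 0.56 (SE 0.15).

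The other MHC class II genes did not follow H2-Ab1. Of the 7 tested members of the MHC class II list, H2-Ab1 alone fell, and none of the other 6 passed. H2-Aa, the gene of the partner alpha chain, was at 54.3 ± 52.1 CPM in WT and 343 ± 404 CPM in dIEC (log2 fold change 1.82, SE 1.19). Cd74, the invariant chain, was at 265 ± 268 and 1044 ± 1085 CPM, and Ciita, the class II transactivator, at 22.3 ± 18.6 and 63.8 ± 58.0 CPM. In males alone the log2 fold changes were -0.016 for H2-Aa, -0.13 for Cd74 and -0.19 for Ciita.

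**Figure D3:**
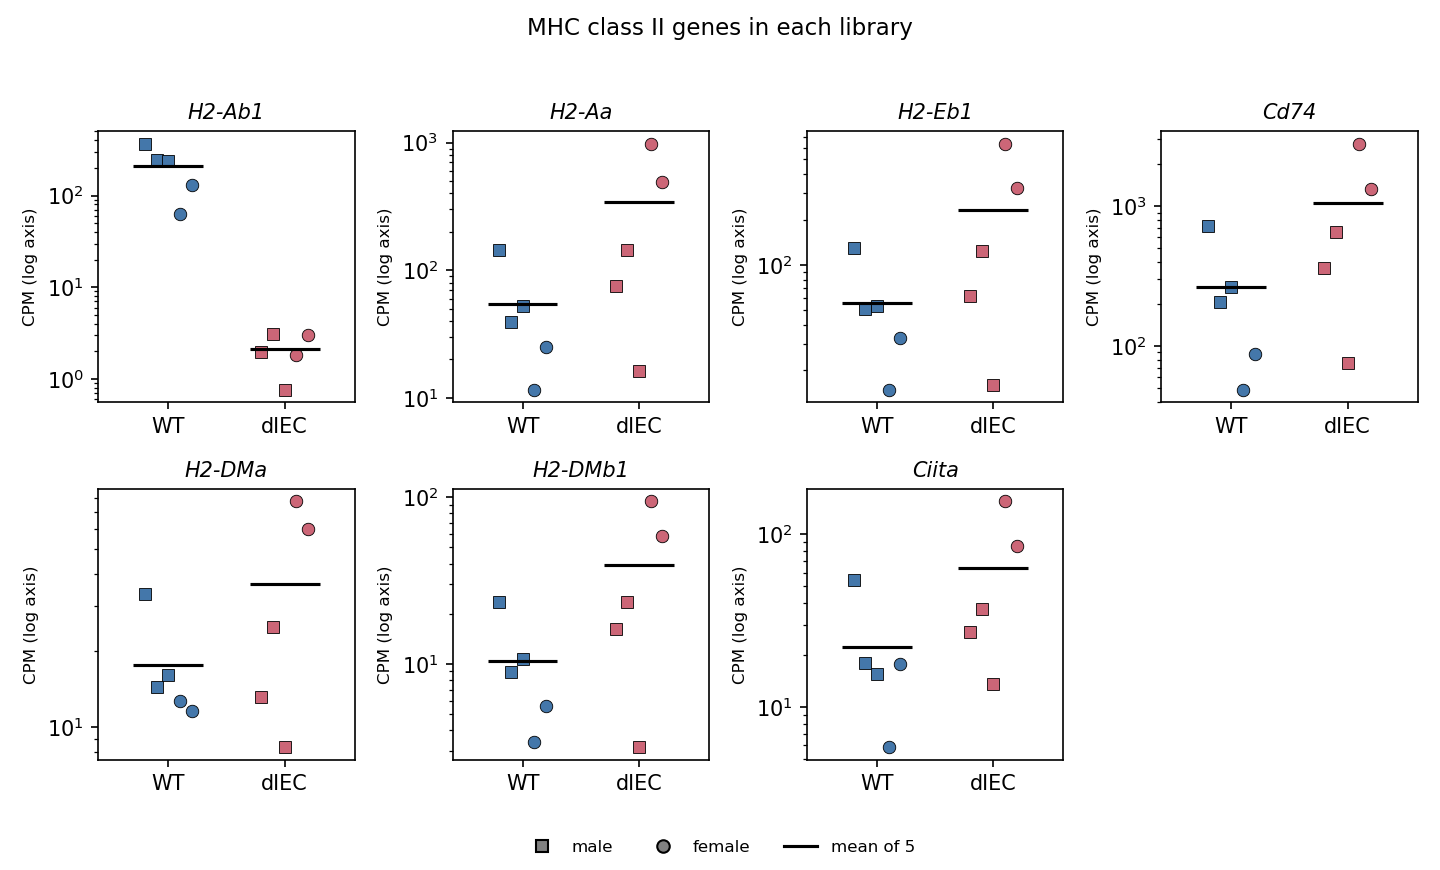
CPM on a log axis for 7 MHC class II genes in each library, with squares for males, circles for females and a line for the mean of 5 per genotype. Both dIEC females lie above every other library for H2-Aa, at 494 and 984 CPM, while H2-Ab1 stays at or below 3.11 CPM in every dIEC library.

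Gene lists fixed in advance were compared with all other genes by camera. With a preset correlation of 0.01, 10 of 31 lists were called, 5 higher and 5 lower in dIEC, and with an estimated correlation 0 were called (lowest adjusted p = 0.494). Of 100 regroupings of the libraries, 69 gave at least 10 called lists, the real one included. All 19 tested interferon gamma response genes were higher in dIEC (median log2 fold change 0.67), among them the guanylate-binding protein gene Gbp6 (1.61, SE 0.55) and Cd274, which encodes PD-L1 (1.67, SE 0.55). All 24 nuclear oxidative phosphorylation genes were lower (median -0.38), among them Sdhb (-0.38, SE 0.14) and Cyc1 (-0.40, SE 0.15), and 25 of 26 xenobiotic metabolism genes were lower (median -0.32), among them Gsta1 (-1.34, SE 0.46). Each of these 3 lists had an adjusted p = 0.494 with an estimated correlation, and 0 of their members passed over all genes or adjusted over the list alone. The interferon gamma median was 1.04 without WT 2, 0.27 without WT 8 and 0.25 without dIEC 7, and the xenobiotic median -0.49 without WT 6, -0.21 without WT 10, -0.53 without dIEC 5 and -0.055 without dIEC 9, each list still called. Without both dIEC 7 and dIEC 9, males alone gave the genotype values. The interferon gamma median was then -0.026 and the xenobiotic median 0.10. In females these medians were 2.25 and -0.98, and that of oxidative phosphorylation -0.63, against -0.20 in males. The WT females had the highest mean log2 CPM of xenobiotic genes (7.51 and 7.43, others at most 7.16). The same held for oxidative phosphorylation genes (8.40 and 7.97, others at most 7.80). For interferon gamma genes they were lowest (1.96 and 2.81, others at least 3.15).

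The remaining called lists were MHC class I (19 of 23 genes higher; adjusted p = 0.518 with an estimated correlation), type I and III interferon response (23 of 25 higher; adjusted p = 0.546) and tuft cell (12 of 14 lower; adjusted p = 0.558). Enteroendocrine (21 of 22 higher), erythroid (4 of 4 higher), unfolded protein response (17 of 19 lower) and proximal small intestine genes (8 of 9 lower) each had an adjusted p = 0.494 with an estimated correlation. With the preset correlation, calls were lost without dIEC 7 for MHC class I (adjusted p = 0.144), type I and III interferon (0.128) and tuft cell genes (0.333). They were lost without WT 8 for type I and III interferon (0.0552) and tuft cell genes (0.101). Without dIEC 9 they were lost for enteroendocrine (0.142), erythroid (0.111) and proximal genes (0.122). The enteroendocrine median then went from 0.31 to 0.12 and the erythroid one from 1.09 to 0.89, while the proximal one went from -0.23 to -0.35. By sex, the erythroid median was 0.020 in males and 7.56 in females. The female value reflects very low counts in the WT females, where the mean log2 CPM of these genes was -2.52 and -2.26. The dIEC females, at 1.96 and 1.63, were near the males, at 0.94 to 1.87. Paneth, goblet, crypt stem, proliferation, mature enterocyte, lipid absorption, cholesterol and clock lists were not called. Few genes of other cell types were listed, with 5 of 15 general leukocyte genes and 2 of 21 T cell genes, and no such list was called apart from the erythroid genes.

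The second comparison, females against males, also checks the sex labels. Xist, the RNA that silences an X chromosome, rose to 685 ± 166 CPM in 4 females from 0.856 ± 0.853 CPM in 6 males (SD; edgeR adjusted p = 3.62e-06). The Y-linked genes Eif2s3y, Kdm5d, Ddx3y and Uty fell. Kdm5d was at 68.3 ± 6.64 CPM in males (SD, n = 6; edgeR adjusted p = 3.44e-07), and Eif2s3y had a count of 0 in every female. These 5 were the genes that passed in edgeR, DESeq2 called 13, and every library matched its label. Kdm6a, an X-linked gene that escapes silencing, was at 109 ± 8.10 CPM in females and 65.0 ± 6.13 CPM in males. It missed the threshold in edgeR (adjusted p = 0.0853) and passed in DESeq2 (adjusted p = 9.52e-09) and limma voom (adjusted p = 0.0107).

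Of the lists, 14 were called between the sexes with the preset correlation and 2, Y-linked and X escape, with an estimated one. Goblet cell genes, of the mucus-secreting cells, were lower in females for 20 of 21 members (camera adjusted p = 0.18 with an estimated correlation). The median log2 fold change was -0.70, or -1.26 within WT and -0.38 within dIEC. None of these 21 passed over all genes in edgeR, and 10 fell adjusted over the list alone. The main mucin gene Muc2 was at 579 ± 447 CPM in females and 1885 ± 1191 CPM in males. Paneth cell genes, of the antimicrobial cells at the crypt base, were lower for 20 of 21, with Lyz1 at 172 ± 144 and 469 ± 207 CPM. Their median was -1.06, or -1.58 within WT and -0.60 within dIEC (camera adjusted p = 0.284 with an estimated correlation). The mean log2 CPM of Paneth genes was lowest in WT female 10 (2.95) and dIEC female 7 (3.13), which also had the lowest proliferation values. It was 4.11 in WT female 8 and 4.89 in dIEC female 9, the latter within the male range of 4.26 to 5.50. Muc2 was chosen after its values were seen. Also called with the preset correlation were enteroendocrine (22 of 22 lower), crypt stem (17 of 18 lower), proliferation (25 of 26 lower), clock (10 of 15 lower), type I and III interferon (23 of 25 lower) and erythroid genes (4 of 4 lower). Nuclear oxidative phosphorylation (24 of 24), mitochondrially encoded (6 of 7), tuft cell (12 of 14) and MHC class I genes (20 of 23) were called higher. With an estimated correlation the adjusted p of these 10 lists ran from 0.353 to 0.681. Their median sex difference changed sign between WT and dIEC for crypt stem (-0.83 and 0.16), proliferation (-0.76 and 0.21) and erythroid genes (-7.04 and 0.31). The same held for type I and III interferon (-0.57 and 0.087) and MHC class I genes (-0.13 and 0.35). The rest of the 10 kept their sign, each with a smaller median in dIEC.

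The third comparison asked whether the difference between genotypes depended on sex. In edgeR 1 gene passed, and DESeq2 called 18. Hbb-bs, a haemoglobin beta chain of red blood cells, had 0 and 2 counts in the 2 WT females and between 76 and 267 counts in the other 8 libraries (edgeR interaction adjusted p = 0.0132). The call was lost when WT 6, WT 8, WT 10, dIEC 3 or dIEC 5 was left out (adjusted p from 0.0644 to 0.385) and with limma voom (adjusted p = 0.118), while DESeq2 called it (adjusted p = 1.22e-08). At an unadjusted p under 0.05 there were 278 genes.

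The MHC class II partner genes had higher values in the 2 dIEC females than in the 2 WT females, a difference on which the tests disagreed. All 7 tested members had a positive interaction, with a median of 4.12 on the log2 scale. All 7 passed adjusted over the list alone, though no member passed over all genes in edgeR. The 7 include H2-Ab1 itself, which was lower in dIEC in both sexes (log2 fold change -5.27 in females, -7.17 in males). Its counts were 754 and 1448 in WT females and 2043 to 4430 in WT males. The median interaction of the 6 partner genes was 4.33. DESeq2 called 5 of these partners over all genes, namely H2-Aa (adjusted p = 0.00366), Cd74 (0.00699), H2-Eb1 (0.0129), H2-DMa (0.0258) and H2-DMb1 (0.0284). H2-Aa was at 18.4 CPM in WT females, 739 CPM in dIEC females, and 78.3 and 78.1 CPM in WT and dIEC males. All 19 interferon gamma genes also had a positive interaction (median 2.07; adjusted p = 0.221 with an estimated correlation), and all 26 xenobiotic genes a negative one (median -1.09; adjusted p = 0.0989). The class II list, H2-Ab1 included, had a camera adjusted p = 0.0989 with an estimated correlation. The erythroid list had 0.0212, or 0.199 with a proliferation score in the model. Its median interaction hardly moved, at 7.55 without the score and 7.57 with it. Of the single genes, the malic enzyme gene Me1 was at 52.9 CPM in WT females and 6.85 CPM in dIEC females, with 8.33 and 8.52 CPM in WT and dIEC males. Nos2, the inducible nitric oxide synthase, was at 19.8 and 305 CPM in these females, with 199 and 222 CPM in males. For both genes the 2 WT females stood apart from the other 8 libraries. Neither passed in edgeR, and DESeq2 called both (adjusted p = 9.59e-07 and 0.00366). These values rest on 2 females of each genotype.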

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

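The tests on Mt1, on antigen-presenting cells, on interferon gamma and on the time of day were chosen after the data were seen, as were those that use a proliferation score, on the crypt to villus axis and in the regroupings for 425 genes. The other regroupings of libraries were set before.

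Mt1 was higher in all 5 dIEC libraries. The 26 tested genes within 1 Mb, Mt2 included, had a median log2 fold change of -0.026, with a range of -0.92 to 1.42. Of these, 2 had an unadjusted p under 0.05 in edgeR. The median argues against a rise shared by most genes of that stretch. It cannot decide on a changed stretch of chromosome that alters Mt1 alone or only a few genes. Induction of both metallothionein genes alike is argued against as well, since the Mt1 log2 fold change exceeded that of Mt2 by 2.51. The combined SE of 0.61 takes the 2 genes as independent. Low counts of Mt2, 5 to 52 in WT and 24 to 81 in dIEC, limit this test too. Over the alternatives the log2 fold change ran from 0.16 to 1.65 for Mt2 and from 3.13 to 3.67 for Mt1. A Cre transgene that carries Mt1 sequence stays open: 4 of 5 dIEC libraries had a higher Mt1 to Mt2 ratio than every WT library, where all 5 were predicted, but the highest WT ratio is of a single library with 5 counts of Mt2. What such low counts can decide was settled for both tests only after their values were known. Induction of Mt1 alone, by the deletion or by Cre itself, was not tested.

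The MHC class II partners of H2-Ab1 were high in both dIEC females. Antigen-presenting cells in the sort are argued against, because such cells keep H2-Ab1, and the H2-Ab1 to H2-Aa ratio of these females was at most 0.237% of the lowest WT ratio. The place on the crypt to villus axis is argued against too, as the median interaction of the 6 partner genes was 4.36 on the log2 scale with a proliferation score in the model and 4.33 without. A response to interferon gamma stays open: the list's interaction had an unadjusted p = 0.0285 with an estimated correlation (adjusted p = 0.221), but its mean log2 CPM was 4.89 in dIEC female 7 and 3.83 in dIEC female 9, the latter within the male range of 3.15 to 3.97, and low in the WT females (1.96 and 2.81). With 2 females per genotype, differences between single mice and an effect of the deletion or of Cre that depends on sex stay open too.

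With a proliferation score as covariate, 425 genes differed between the sexes instead of 5. In 1 of 100 regroupings, the real one, the count was as large, and the highest other was 76. However, the score was chosen after the data were seen, and the other regroupings had no term for sex in the model. Chance is therefore not excluded for this count. Time of day stays open: clock genes of opposite phase differed by 0.063 (SE 0.092) on the log2 scale, but 5 of the 6 clock genes called, Per1 and Cry2 among them, were in neither set. Sex itself and an unrecorded difference in handling, which could coincide with sex, stay open and untested.

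In 100 regroupings of the libraries, the 2 genes of dIEC against WT were matched by 3, the real one included, with 3745 genes as the highest other, and the 5 genes between the sexes by 2, with 5003 as the highest other. These shares cannot decide on chance, because both counts hold genes that the true grouping sets by itself. H2-Ab1 was the gene to be deleted in dIEC, and the genes called between the sexes were Xist and Y-linked genes. The genotype count does not test Mt1 apart from H2-Ab1. The regroupings with 3685, 3745 and 5003 genes put together libraries from the proliferative end of the first component, which points to that structure. The 10 lists called between genotypes were matched by 69 regroupings, with 19 as the highest other, so chance cannot be excluded for that count.

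Single libraries stood apart in 7 of 194 groups examined, where chance gives about 9.70. The gap as a share of the range was 0.789 for Ifit2 in dIEC (female 7 low), 0.724 for Uqcrc1 in dIEC (male 1 low), 0.774 for Scg2 in WT (female 8 low) and 0.729 in dIEC (female 7 low). It was 0.954 for Hspa5 in dIEC (female 9 high), 0.723 for Mt2 in dIEC (male 1 high) and 0.735 for the MHC class I list in dIEC (female 7 high).

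A genotype by sex interaction was called for Hbb-bs (edgeR adjusted p = 0.0132) and, with the preset correlation, for 15 lists. With an estimated one the erythroid list alone passed (camera adjusted p = 0.0212). It did not pass with a proliferation score in the model (0.199), though its median interaction was 7.57 with the score and 7.55 without. Hbb-bs had 0 and 2 counts in the 2 WT females, and limma voom did not call it (adjusted p = 0.118). An effect of genotype that depends on sex is thus not shown. Among the 15 lists, the preset adjusted p was 2.33e-23 for xenobiotic and for erythroid genes, 7.38e-19 for MHC class II and 2.79e-17 for interferon gamma. It was 6.52e-11 for goblet, 2.05e-10 for oxidative phosphorylation and 4.52e-08 for MHC class I. It was 2.15e-05 for type I and III interferon, 3.87e-05 for lipid absorption, 0.000143 for enteroendocrine, 0.000398 for crypt stem, 0.00411 for proliferation, 0.00787 for Paneth and for proximal small intestine genes, and 0.0332 for mature enterocyte genes.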

How the results depend on the processing

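No paired analysis was run, because the labels name no pairs. Their replicate numbers run on through both genotypes, so they neither show nor exclude pairs. The proliferation score, the residual component, the fit without dIEC 7 and dIEC 9 and DESeq2 on every listed gene were chosen after seeing the data. H2-Ab1 kept its call in 24 of 26 alternatives. Of 1941 values of the other named genes and lists, 1867 kept direction and side of the threshold, 32 lost and 28 gained a call, and 14 reversed. Most of the 1941 were of genes not called in the main fit, which had no call to lose. The share that kept its side therefore says little about the calls. Of the losses, 1 was of Mt1 and 6 were of Hbb-bs, and the others were of gene lists. When each library was left out in turn, 2 genes were called between genotypes every time, H2-Ab1 stayed between -6.83 and -6.06 on the log2 scale, 5 to 6 genes were called between the sexes, 8 to 14 lists between genotypes, and 0 to 1 interaction genes. Where 1 female of a genotype was left, it is assumed to vary like the other groups. DESeq2 called 4 genes between genotypes, 13 between the sexes and 18 for the interaction, 5 of these MHC class II genes, and on every listed gene 3 and 9. limma voom called 0 interaction genes, with 99 at an unadjusted p under 0.05. In females only, with fewer samples, 0 genes were called between genotypes in edgeR, with 123 at an unadjusted p under 0.05; H2-Ab1 was at -5.27 (adjusted p = 0.544) and Mt1 at 3.13 (adjusted p = 0.713, the highest of its alternatives, the lowest being 2.56e-43). In males only, values turned negative for H2-Aa (-0.016), H2-Eb1 (-0.22), H2-DMa (-0.48), H2-DMb1 (-0.036), Cd74 (-0.13) and Ciita (-0.19). An estimated correlation left 0 of 10 lists. With the proliferation score 4 genes differed between genotypes, 425 between the sexes and 10 for the interaction. With the first residual component as covariate 1 gene, Mt1, was called, and H2-Ab1 was at -6.42 (adjusted p = 0.0525; over all alternatives from 8.72e-44 to 0.544). With dIEC 7 and dIEC 9 left out, 8 genes were called between the sexes and 6 lists between genotypes, 2 of them among the 10. No dIEC female then remained, so the genotype values again came from males alone and the sex values from WT alone. The same genes were negative here as in the males-only fit, which this fit nearly repeats. H2-Aa was at -0.0026, H2-Eb1 at -0.21, H2-DMa at -0.46, H2-DMb1 at -0.024, Cd74 at -0.12 and Ciita at -0.17. The xenobiotic list had a median of 0.10 and the erythroid list one of 0.018, both with the opposite direction in camera. Apart from the smaller samples and the missing dIEC females, the cause was not tested. In the simulation, 4.62% of genes changed 1.5-fold between genotypes were found, so changes of that size were mostly not detectable. Its genes varied independently, unlike the real ones, which share an axis, so its rates are a rough guide.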

Other observations

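The tests in this part were chosen after the data were seen. With a proliferation score in the model, 132 genes were higher and 293 lower in females (edgeR adjusted p under the threshold). Among them were 9 of 24 nuclear oxidative phosphorylation genes, all higher, such as Cox4i1 (log2 fold change 0.53, SE 0.12) and Uqcrc2 (0.57, SE 0.13). The chaperone genes Hspa5 (0.51, SE 0.13) and Calr (0.43, SE 0.11) were higher too. The clock genes Per1 (-1.02, SE 0.20), Cry2 (-0.91, SE 0.18) and Bhlhe40 (-0.80, SE 0.11) were lower, as was the interferon-induced gene Rsad2 (-1.05, SE 0.25). Of the lists, Y-linked and X escape genes passed with an estimated correlation and that score, while the clock list (adjusted p = 0.318) and the oxidative phosphorylation list (adjusted p = 0.482) did not.

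The proliferation list was set against 3 other lists over 10 libraries. Its mean log2 CPM ran against that of mature enterocyte genes (Pearson r = -0.913, permutation p = 0.00022, adjusted p = 0.00022; Spearman rho = -0.891, permutation p = 0.00116) and of lipid absorption genes (r = -0.876, permutation p = 0.00018, adjusted p = 0.00022; rho = -0.903, permutation p = 0.0005). It ran with that of crypt stem cell genes (r = 0.975, permutation p = 4e-05, adjusted p = 0.00012; rho = 0.976, permutation p = 4e-05). Without WT female 10 and dIEC female 7, the libraries farthest from the median proliferation value, r was -0.889, -0.853 and 0.935 in the same order. In the 6 males r was -0.928, -0.771 and 0.936 (exact permutation p = 0.00556, 0.05 and 0.00833), and rho was -0.943, -0.714 and 0.943 (p = 0.0167, 0.136 and 0.0167), so the lipid relation did not pass in males by rank. In the 5 WT libraries r was -0.892, -0.929 and 0.952 (p = 0.133, 0.0333 and 0.0333) and rho -0.60, -0.90 and 0.90 (p = 0.35, 0.0833 and 0.0833). In the 5 dIEC libraries r was -0.939, -0.834 and 0.996 (p = 0.0167, 0.0333 and 0.0167) and rho -1, -0.90 and 1 (p = 0.0167, 0.0833 and 0.0167). No batch is given in the labels.

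The deposited table opens with 12 genes that stand ahead of rows in chromosome order. They are Mt1, H2-Ab1, Sestd1, Fgf15, Abcc3, Ckb, Bid, Bmp2, Gne, Ociad2, Mrpl4 and Acer1. All 12 had an unadjusted p under 0.05 between genotypes in edgeR, the highest being 0.0136, with 6 higher and 6 lower in dIEC. The meaning of this order is not stated in the sources used here, and Mt1 and H2-Ab1 alone among them passed the adjusted threshold.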
